A study of Homo sapiens with 6 samples.

How the data were processed

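RNA of HK-2 cells was sequenced from 6 libraries made with an NEBNext Ultra kit, per the labels. The authors deposited 1 table of FPKM (fragments per kilobase of gene length, scaled to each library's total) with 1 column per library and a gene length column. Alignment with HISAT2 2.0.5 to GRCh38 and counting with featureCounts 1.5.0-p3 are named in the submitters' processing notes. The annotation release, strand setting and filters are not given in the sources used here. Gene identifiers, starts and ends of all 58735 genes matched GENCODE 29.

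GLT columns carry the group word and replicate number of their titles. The other 3 columns are headed BA with a replicate number, which was read as butyrate because NaB is the only other group, so the direction of every difference rests on this reading. No other column of values was found. The labels do not say that replicates are separate cultures, so p-values measure the spread between these libraries, which can be technical. The protocol text is identical for both groups and names NaB and GLT doses alike, so that NaB was absent from GLT samples, and GLT present with NaB, was read from titles and treatment labels. The deposited FPKM times gene length were whole multiples of 1 step per library, within 0.05 of a whole number for 100% of values above 0. The rebuilt fragments gave 14712953 to 15616584 per library in listed genes, and the authors' totals for scaling came to 14957182 to 16626708. No spike-in was used here, so changes are relative to the library. Pairs of libraries in a group differed by more than sampling noise (chi-square per gene 1.74 to 18.0, where 1 is noise), so each was used as 1 sample.

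Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1), with FPKM as the authors scaled it, by limma 3.58.1 with a mean-variance trend in R 4.3.3. P-values were two-sided and adjusted by Benjamini-Hochberg over 13352 genes, with calls at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. FPKM are not counts, so no count model was the main test. The test, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were 10 fixed from the series title or its readout, the 12 protein-coding genes that rose most and the 12 that fell most with groups that did not overlap, and up to 3 raised and 3 lowered members of each list (the member of smallest p where none passed); some of these are not reported here. Lists with at least 5 tested members were tested with camera at a correlation of 0.01, and with an estimated correlation and fry as alternatives. Shares of FPKM were compared by exact permutation, whose smallest p for 3 against 3 libraries is 0.1. GC content was that of each gene's longest GENCODE 29 transcript, known for 13345 tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

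The steps were tested on simulated data: counts drawn for the real genes from the real means and library sizes at 1 dispersion for all genes, with 200 genes changed by known folds, of 13380 tested. At 1.3-fold, 22.9% of changed genes were recovered, at 1.5-fold 61.2%, at 2-fold 91.7% and at 3-fold 95.8%, and 2.96% of calls were unchanged genes. No simulated library deviated by gene GC content as NaB replicate 2 did in the real data, so the rates for the real libraries may differ. Alternatives were other pseudocounts, filters, scalings and variance models, a replicate block, limma-voom on rebuilt fragments, and each library left out. Added after seeing the data were a GC correction (loess span 0.3 per library), that correction with the block, and scaling to the fragments of the listed genes.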

Results

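RNA-seq was carried out on HK-2 cells, an established line of human proximal tubular epithelial cells. By the labels, 6 libraries came from cells under the condition named GLT, with 25 mM glucose and 250 µM PA for 24 h as the doses given. For 3 of them the labels add sodium butyrate (NaB, 1 mM), the salt of a short-chain fatty acid and a known inhibitor of histone deacetylases. The 2 groups are called GLT and GLT with NaB, with n = 3 libraries each. The deposited table lists FPKM for 58735 genes, with GRCh38 coordinates. Whole fragments could be rebuilt from these values, and the libraries held 14712953 to 15616584 fragments in listed genes. The treatment labels of these 3 name NaB and GLT together while their titles name NaB alone, and GLT in them is a reading of the treatment labels. On that reading no sample without GLT was analysed here, and the values do not show what GLT itself did.

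The question behind the comparison, as the series states it, is how NaB acts on lipid accumulation in tubular cells under GLT, with PP2A and TFEB named in the series title. The values here are of RNA, and they do not measure lipid content, PP2A activity or TFEB protein. With NaB, PLIN2, which encodes the coat protein of lipid droplets, rose from 51.3 ± 2.36 to 85.6 ± 5.47 FPKM (SD, n = 3 per group). CPT1A, the gene of the enzyme that admits long-chain fatty acids to mitochondria, rose from 5.07 ± 0.245 to 7.45 ± 0.447 FPKM. PPP2R1A, a scaffold subunit of the phosphatase PP2A, fell from 33.4 ± 0.377 to 23.5 ± 3.03 FPKM, while TFEB, a transcription factor of lysosomal genes, stood at 1.35 ± 0.250 FPKM in GLT and 1.07 ± 0.102 with NaB and did not pass the test. CCL20, IL6 and TNF, which encode cytokines, rose, and AURKA and PLK1, which encode kinases of mitosis, fell.

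Across the transcriptome, 3147 of 13352 tested genes passed an adjusted p of 0.05 in limma, 1278 higher and 1869 lower with NaB. The raised share was 40.6% under the authors' scaling and 50.9% under median-ratio scaling, where 1512 genes were higher and 1459 lower. Changes of at least 2-fold on the log2(FPKM + 1) scale were found in 104 genes, 94 of them higher and 10 lower. The genes changed by NaB at least 2-fold numbered 254 with a pseudocount of 0.1, 278 with 0.01, 225 as TPM, 290 with limma-voom and 37 at a mean FPKM of at least 5. The 3 values of one group all lay on one side of the other group's in 5881 tested genes, or 44.0%, where chance gives 10%. The number of called genes depended on the libraries: it was 1444 without GLT replicate 1, 1348 without GLT replicate 2, 1333 without GLT replicate 3, 1761 without NaB replicate 1 and 5204 without NaB replicate 2. Without NaB replicate 3 the lowered genes numbered 1183. NaB replicate 2 stood apart from the other NaB libraries on the second principal component, at -21.9 where the others were at 10.6 or above, while the first component (50.6% of the variance) separated the groups.

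**Figure D1:**
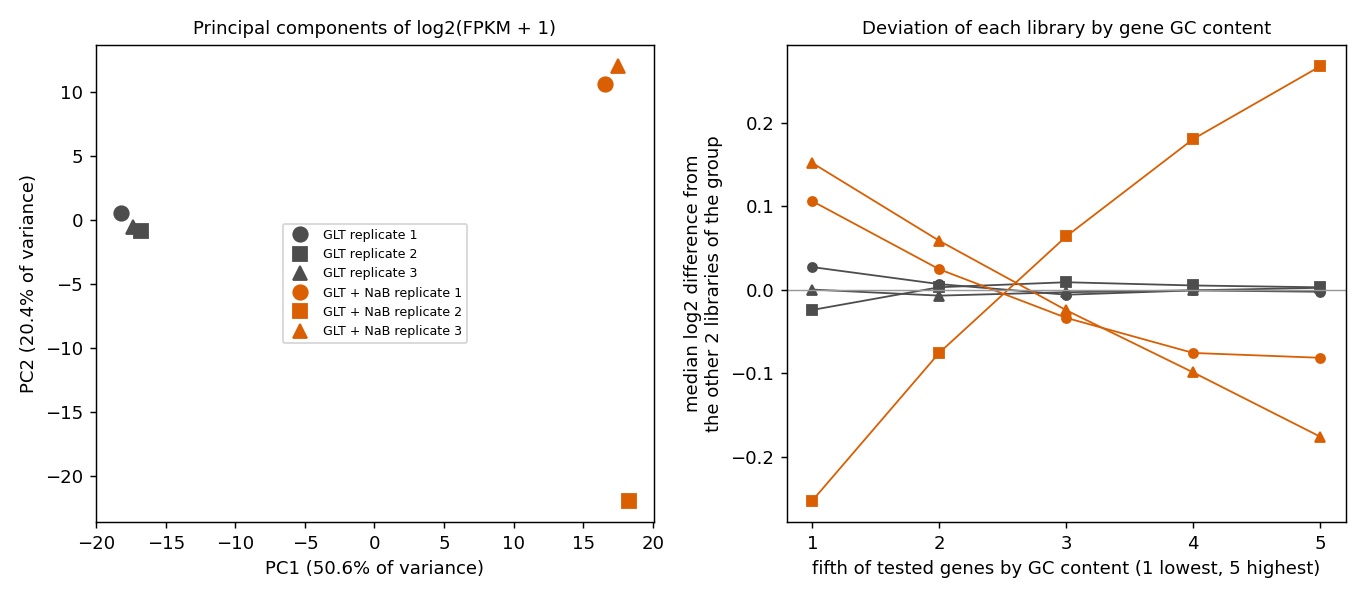
Left, each of the 6 libraries on the first and second principal components of log2(FPKM + 1), in arbitrary units; right, each library's median log2 difference from the other 2 libraries of its group in 5 equal groups of the tested genes by GC content. The groups part on the first component, and NaB replicate 2 runs from -0.25 in the group of lowest GC content to 0.27 in that of the highest.

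Among protein-coding genes whose groups did not overlap, the largest rises were those of SSC4D and PADI3. SSC4D (ENSG00000146700, chromosome 7, 76389334 to 76409695) rose from 1.96 ± 0.0788 to 24.5 ± 2.42 FPKM, a log2 fold change of 3.10 ± 0.08 (SE; adjusted p = 1.64e-05, limma). PADI3 (ENSG00000142619, chromosome 1, 17249098 to 17284233), the gene of a peptidylarginine deiminase, rose from 3.47 ± 0.389 to 23.2 ± 2.36 FPKM. Next came CCL20, TNNC1, CYP24A1, OLFML2A, NCCRP1, LCN2, IL6, PRSS8, TNF and CLDN4, with log2 fold changes from 2.03 down to 1.61. CYP24A1, whose product degrades active vitamin D, rose from 16.0 ± 0.569 to 60.5 ± 3.10 FPKM. The 12 largest falls were smaller and ran from -1.13 in LANCL2 to -0.92 in HMGN2, through CAVIN3, TM4SF18, CDH6, PHF19, MPDU1, ATF5, CAP2, GTF3C6, USP5 and DPP3. LANCL2 (ENSG00000132434, chromosome 7, 55365448 to 55433742) fell from 10.0 ± 0.317 to 4.07 ± 0.338 FPKM (adjusted p = 0.000609, limma). Exons of ATF5 overlap NUP62 on the opposite strand over 21.2% of their bases and those of IL6 overlap AC073072.1 over 20.7%. The strand setting of the counting is not given in the sources used here, so how such fragments were assigned is unknown.

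Of the genes named from the series title or its readout, 5 passed the test. PLIN2 (ENSG00000147872, chromosome 9, 19108375 to 19149290) had a log2 fold change of 0.73 ± 0.07 (SE; adjusted p = 0.00144, limma). CPT1A (ENSG00000110090, chromosome 11, 68754620 to 68844410) had 0.48 ± 0.07 (adjusted p = 0.00439), and CDKN1A, the gene of the cell cycle inhibitor p21, rose from 59.3 ± 3.91 to 84.0 ± 8.13 FPKM (adjusted p = 0.00872). PPP2R1A (ENSG00000105568, chromosome 19, 52190039 to 52229533) had -0.50 ± 0.09 (adjusted p = 0.00988). PPP2CB, a catalytic subunit of PP2A, fell with a log2 fold change of -0.27 ± 0.07 (adjusted p = 0.0276), a call that was lost under median-ratio scaling (adjusted p = 0.0598, range over 21 alternatives 0.0103 to 0.116) and without GLT replicate 1 (0.103), GLT replicate 2 (0.0926), GLT replicate 3 (0.104) or NaB replicate 1 (0.0807). PPP2CA, the other catalytic subunit, stood at 27.5 ± 0.480 FPKM in GLT and 23.3 ± 1.84 with NaB (adjusted p = 0.0505, range 0.00547 to 0.225). PPP2CA passed in 5 of the 21 alternatives. These were without NaB replicate 2 (limma adjusted p = 0.0112), a mean FPKM of at least 5 (0.0399) and protein-coding genes only (0.0360). The others were a GC correction (0.00547) and that correction with a replicate block (0.0234), both chosen after seeing the data. TFEB had a log2 fold change of -0.18 ± 0.11 (adjusted p = 0.293) and TFE3, its relative, -0.15 ± 0.11 (adjusted p = 0.348). Without NaB replicate 2, TFE3 had -0.27 and passed (adjusted p = 0.00501, range 0.00501 to 0.682). SREBF1, a regulator of fatty acid synthesis genes, had -0.11 ± 0.10 (adjusted p = 0.488), and HAVCR1, the gene of the injury marker KIM-1, had -0.03 ± 0.05 (adjusted p = 0.684).

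**Figure D2:**
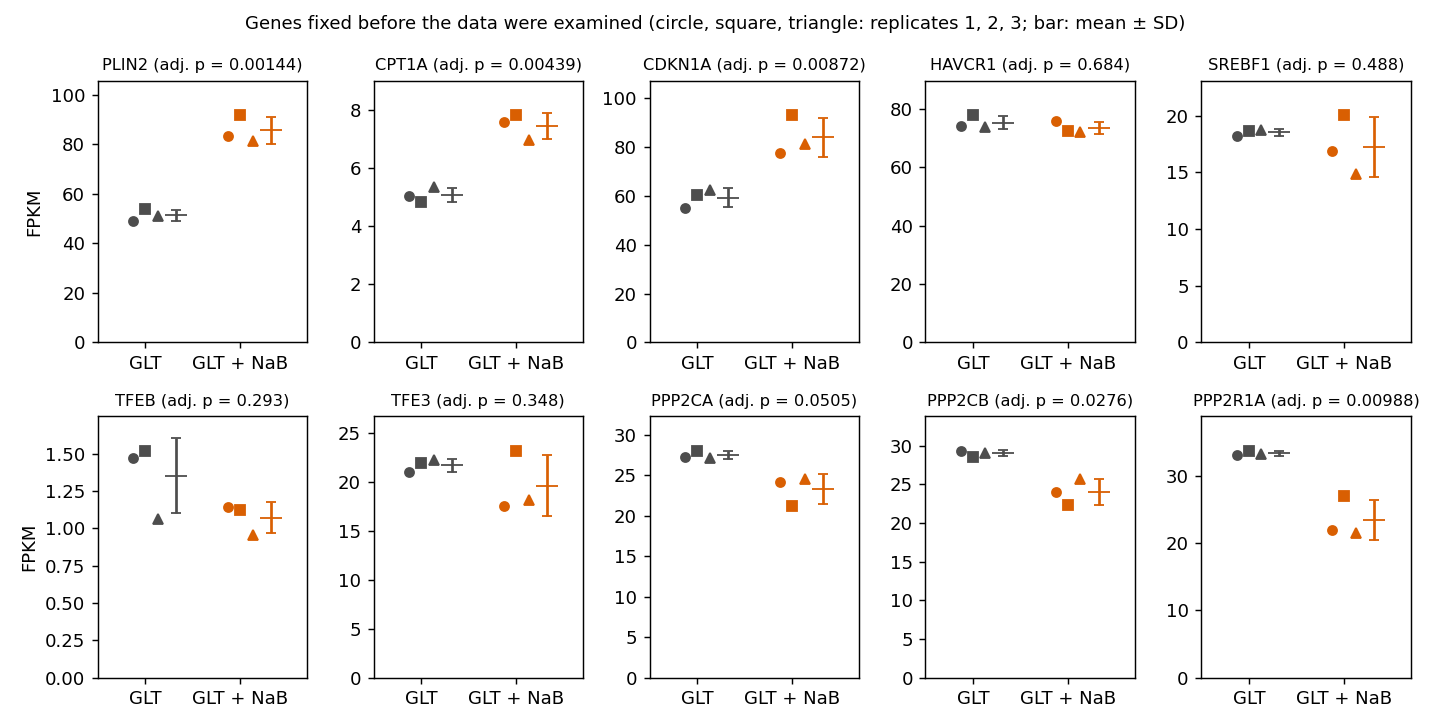
FPKM of the 10 genes named from the series title or its readout in each library (circles, squares and triangles for replicates 1, 2 and 3), with the mean and SD of each group of 3 beside them. PLIN2, CPT1A and CDKN1A lie higher in every NaB library than in any GLT library, and PPP2R1A, PPP2CA and PPP2CB lie lower, although PPP2CA did not pass the test.

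Of 28 gene lists fixed before the data were examined, 27 had enough tested members, and 5 passed the limma camera test with a preset correlation between genes. With an estimated correlation 0 lists passed in camera, 0 at an unadjusted p under 0.05, and each of the 5 had an adjusted p = 0.795. Fry passed 9 lists, 4 of the 5 among them, but not extracellular matrix and fibrosis. Other splits of the 6 libraries into 3 and 3 passed up to 7 lists in camera with the preset correlation. Every other split mixes GLT and NaB libraries in both of its groups, so a part of a NaB difference can stay in it. The number of lists past that test therefore neither sets the NaB contrast apart nor speaks against it. In the inflammation list 11 of 22 tested genes rose, 0 fell and 11 did not pass, with a median log2 fold change of 0.39 (camera adjusted p = 1.13e-05). CCL20, a chemokine, rose from 6.92 ± 0.956 to 31.6 ± 5.92 FPKM, IL6 from 24.1 ± 3.41 to 78.7 ± 17.4, and TNF from 2.68 ± 0.760 to 10.6 ± 3.45. Adjusted over the list alone, 12 rose and 0 fell. In the list of proliferation genes, 17 of 37 fell, 2 rose and 18 did not pass (median -0.20, camera adjusted p = 0.00941). The largest falls in the list were those of AURKA at a log2 fold change of -0.84 ± 0.07, PLK1 at 30.4 ± 1.89 FPKM in GLT and 17.3 ± 1.93 with NaB, and KIF20A at 28.5 ± 1.12 and 16.2 ± 1.34. The 2 that rose were CCNE1, a cyclin of the G1 to S transition (log2 fold change 0.42), and MCM6, a subunit of the replicative helicase (0.21). Adjusted over the list alone, 18 fell and 3 rose.

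The cholesterol synthesis and uptake list passed with 4 of 24 genes higher, 0 lower and 20 not past (median 0.14, camera adjusted p = 0.00961), and the same numbers adjusted over the list alone. The numbers higher and lower were 6 and 0 under median-ratio scaling and 12 and 1 with a GC correction chosen after seeing the data. HMGCS1, an early enzyme of the pathway, rose from 31.3 ± 1.24 to 42.1 ± 3.65 FPKM, TM7SF2, a sterol reductase, had a log2 fold change of 0.40, and SREBF2, the regulator of the pathway, 0.36. In the extracellular matrix and fibrosis list 10 of 30 genes rose, 3 fell and 17 did not pass (median 0.09, camera adjusted p = 0.0330). The collagen gene COL5A1 rose from 1.12 ± 0.122 to 2.97 ± 0.340 FPKM and COL1A1 from 3.40 ± 0.353 to 6.83 ± 1.09, while TAGLN, TGFBR1 and VIM fell. Adjusted over the list alone, 12 rose and 3 fell, and the list did not pass with fry (adjusted p = 0.0893). In the list of genes known to respond to deacetylase inhibitors 5 of 13 rose, 1 fell and 7 did not pass (median 0.19, camera adjusted p = 0.0330), also when adjusted over the list alone. H1F0, a linker histone gene, rose from 118 ± 5.55 to 219 ± 14.9 FPKM, CLU from 15.9 ± 1.20 to 24.7 ± 2.50 and TXNIP with a log2 fold change of 0.63 ± 0.11, while MT2A fell, a call lost under median-ratio scaling. The calls of the last 2 lists were lost without NaB replicate 2 (adjusted p = 0.158 and 0.0859) and without GLT replicate 1 (0.0920 and 0.181), in a range over 16 alternatives of 0.00145 to 0.795 for the first and 0.00604 to 0.795 for the second. They were lost as well with a correction for GC content chosen after seeing the data (0.0550 for both), under which their medians were no smaller, at 0.13 and 0.24, and regained with that correction and a replicate block (0.0453 and 0.0412).

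**Figure D3:**
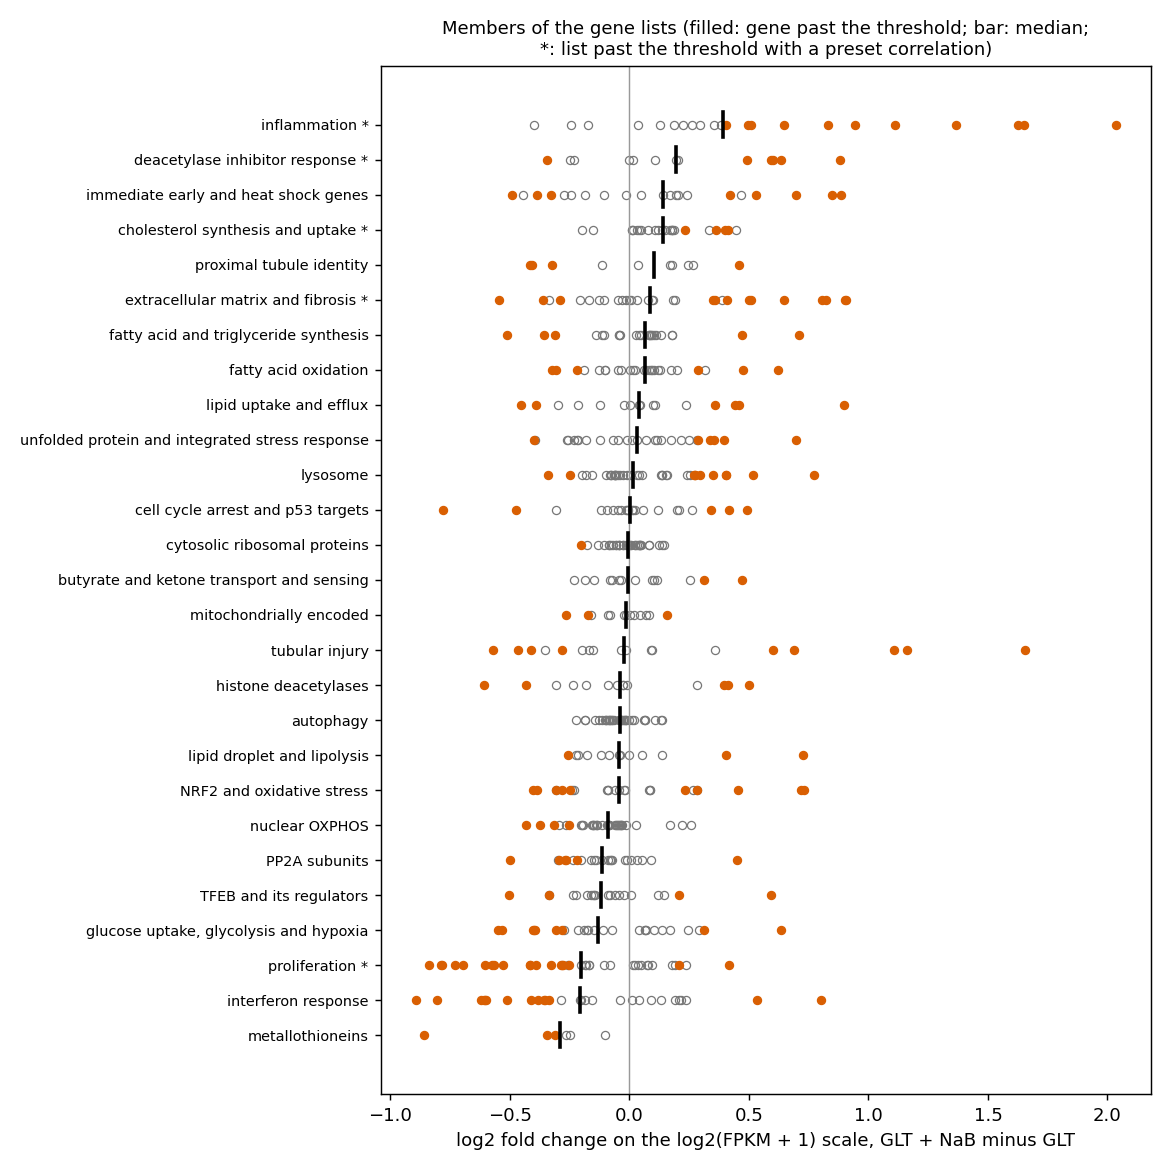
Log2 fold change, GLT with NaB minus GLT, of each tested member of 27 gene lists, filled where the gene passed the test, with the list's median as a bar and an asterisk where the list passed with a preset correlation. The inflammation list has its median at 0.39, and no member of the autophagy list passed.

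For the lists closest to the series title, the autophagy list had 0 of 36 members past the threshold in either direction, also when adjusted over the list alone, with 4 lower and 0 higher at an unadjusted p under 0.05 and 0 calls by limma-voom, but 1 lower with the GC correction chosen after seeing the data. Its smallest p belonged to BNIP3, at 21.1 ± 0.197 FPKM in GLT and 18.4 ± 0.772 with NaB (adjusted p = 0.0519, limma). In the lysosome list 9 of 38 genes rose, 2 fell and 27 did not pass (median 0.02, camera adjusted p = 0.0812), and adjusted over the list alone 10 rose and 2 fell. GAA, the lysosomal acid glucosidase, rose from 5.45 ± 0.240 to 10.1 ± 1.43 FPKM, NEU1 and CTSF rose, and CTSL and ATP6V1B2 fell. The lysosome list passed in 6 of 16 alternatives (adjusted p from 0.00546 to 0.795). In camera these were median-ratio scaling (0.0469), quantile normalization (0.00546) and a mean FPKM of at least 5 (0.00604). The others were without NaB replicate 1 (0.0413), without NaB replicate 3 (0.0318), and scaling to the listed genes, chosen after seeing the data (0.0413). The list did not pass without NaB replicate 2 (0.373) or with fry (0.254). With the GC correction 15 of its genes rose and 2 fell, and it did not pass (camera adjusted p = 0.0550). Of TFEB and its regulators, 2 of 20 rose and 2 fell (camera adjusted p = 0.509), with 2 and 3 adjusted over the list alone, and the list passed downward with fry, which does not compare it with other genes (adjusted p = 0.0276). RRAGD, a Rag GTPase gene, rose from 1.01 ± 0.0752 to 2.04 ± 0.158 FPKM and RRAGA rose, while MTOR fell from 15.6 ± 0.452 to 12.1 ± 0.750 and RPTOR fell from 9.49 ± 0.131 to 6.46 ± 1.12. Among PP2A subunits and partners 1 of 23 rose and 5 fell (camera adjusted p = 0.248), with 1 and 6 adjusted over the list alone 1 and 1 under median-ratio scaling and 1 and 8 with the GC correction, and this list too passed downward with fry (0.0276). PPP2R5B rose, and PPP2R1A, the activator PTPA and the inhibitor SET fell, SET from 176 ± 3.01 to 146 ± 11.5 FPKM. Under median-ratio scaling PPP2R1A was the only lowered call that stayed (limma adjusted p = 0.0104), and those of PTPA and SET were lost.

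Fatty acid oxidation had 3 of 26 genes higher and 3 lower (camera adjusted p = 0.329): ANGPTL4, CPT1A and ACSL1 rose, while EHHADH, ACADVL and ECI2 fell. Fatty acid and triglyceride synthesis had 2 of 24 higher and 3 lower (0.491), with SCD5 and ACSS2 higher and FADS2, ELOVL1 and GPAM lower. Lipid droplet and lipolysis genes had 2 of 13 higher, PLIN2 and HILPDA, and 1 lower, MGLL, the monoglyceride lipase, whose call was lost under median-ratio scaling. Their median was -0.04 and their mean 0.01, with the test upward (0.900). Lipid uptake and efflux had 4 of 16 higher and 2 lower (0.476), and LRP1, a lipoprotein receptor, rose from 9.31 ± 0.525 to 18.3 ± 2.57 FPKM. Adjusted over each list alone, the counts were 3 and 3, 2 and 3, 2 and 1, and 5 and 4. Under median-ratio scaling they were 4 and 2, 2 and 1, 2 and 0, and 5 and 1. With scaling to the fragments of the listed genes, chosen after seeing the data, fatty acid oxidation had 5 and 1, and with the GC correction 7 and 3.

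Interferon response genes had 12 of 28 lower and 2 higher, and the list did not pass in camera (median -0.21, adjusted p = 0.125) but did with fry, downward (0.0443). Adjusted over the list alone 13 fell and 4 rose, and 12 were lower and 5 higher under median-ratio scaling, 10 and 5 under quantile normalization. OAS2 fell with a log2 fold change of -0.89 ± 0.09 and IFIH1, a sensor of double-stranded RNA, from 14.0 ± 1.52 to 8.76 ± 0.162 FPKM, whereas CXCL10 rose from 2.89 ± 0.264 to 5.78 ± 0.484. Tubular injury genes had 5 of 18 higher and 4 lower, with a median of -0.02 against a mean of 0.17 and an upward test (adjusted p = 0.509), and 6 and 4 adjusted over the list alone. LCN2, the gene of the injury marker NGAL, rose from 6.95 ± 1.14 to 24.3 ± 5.40 FPKM and GDF15 from 112 ± 1.38 to 254 ± 34.3, while SPP1 fell from 553 ± 23.2 to 400.4 ± 9.60 and CD44 fell. Of 33 proximal tubule identity genes, only 10 reached the filter on mean FPKM and were tested. Among these 10, 1 was higher, AMN, and 3 were lower, among them GGT1 and SLC4A4 (camera adjusted p = 0.578). The counts were the same adjusted over the list alone, 3 and 3 by limma-voom and 4 and 3 with the GC correction. Exons of ITGB6, which fell, overlap AC092153.1 on the same strand over 20.6% of their bases. Those of AMN, at a mean of 1.07 FPKM, overlap CDC42BPB (22.3 FPKM) on the opposite strand over 16.4%. Of 30 markers of other kidney and non-epithelial cell types, 28 lay below the filter, none above 1.08 FPKM in any library, and the 2 tested, SCNN1A and PODXL, rose.

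The other lists did not pass the camera test with all 6 libraries under the authors' scaling. Unfolded protein and integrated stress response genes had 5 of 27 higher and 1 lower, with ATF3 higher and CHAC1 lower. NRF2 and oxidative stress genes had 5 of 25 higher and 5 lower, with SOD2 and HMOX1 higher and KEAP1 and SOD1 lower, and a median of -0.04 against a mean of 0.02 and an upward test. Glucose uptake, glycolysis and hypoxia genes had 2 of 26 higher and 7 lower: TXNIP and PFKFB3 rose, while PKM fell from 337 ± 4.22 to 230.3 ± 21.8 FPKM and HK2 and ENO1 fell. In this list 4 were higher and 7 lower under median-ratio scaling, and 6 and 9 with the GC correction. Cell cycle arrest and p53 targets had 3 of 22 higher, among them BTG2, and 2 lower, TP53I3 and FAS. Of the histone deacetylases 3 of 14 rose, with HDAC1 going from 90.3 ± 2.36 to 119 ± 4.25 FPKM, and 2 fell, HDAC7 and SIRT5. Among butyrate and ketone transport genes 2 of 14 rose, ACSS2 and the transporter gene SLC16A1, and 0 fell, with a median of -0.01 against a mean of 0.04 and an upward test. Metallothionein genes had 0 of 6 higher and 3 lower, and 2 lower under median-ratio scaling, with MT1M at 21.5 ± 0.906 FPKM in GLT and 11.5 ± 2.27 with NaB (camera adjusted p = 0.0812). The metallothionein list passed without GLT replicate 1 (0.0252, range over 16 alternatives 0.0252 to 0.795) and downward with fry (0.0485). Immediate early and heat shock genes had 5 of 21 higher, led by IER3 and DUSP1, and 3 lower, BAG3, HSPH1 and HSP90AA1. Nuclear OXPHOS genes had 0 of 36 higher and 4 lower, among them NDUFS3 and MFN2, whereas under TPM 2 were higher and 4 lower, and the list passed downward with fry (0.0276). Fry was run only under the authors' scaling, and the median of this list was -0.09 there and -0.02 under quantile normalization. Cytosolic ribosomal protein genes had 0 of 34 higher and 1 lower, RPS27A, with a median of -0.01 against an upward test, and under quantile normalization 4 were higher and 1 lower. Mitochondrially encoded genes had 1 of 13 higher, MT-CO1, and 2 lower, MT-ND3 and MT-ATP6, with a median of -0.01. Under median-ratio scaling 1 was lower and the median was 0.03, and under TPM and quantile normalization 0 were lower. Their share of FPKM was 15.9% ± 0.357 in GLT and 16.1% ± 0.493 with NaB (two-sided exact permutation p = 0.8, n = 3 per group, where 0.1 is the smallest possible). The 10 highest genes held 15.6% ± 0.206 and 16.1% ± 0.441 of FPKM (exact permutation p = 0.2). Adjusted over the list alone, the numbers higher and lower were 5 and 1 for stress responses, 5 and 5 for NRF2, 4 and 8 for glycolysis, 3 and 2 for p53 targets and 3 and 2 for deacetylases. Adjusted likewise, they were 2 and 0 for butyrate transport, 0 and 4 for metallothioneins, 5 and 4 for immediate early genes, 0 and 2 for OXPHOS, 0 and 0 for ribosomal proteins and 1 and 2 for mitochondrially encoded genes.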

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

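The tests in this part were chosen after the results were seen, except the test of which group NaB replicate 2 resembles. The fragments outside the listed genes, which have no gene of their own in the deposited table, made up 4.83% of the authors' total in the NaB libraries (SD 2.37) and 1.45% in GLT (SD 0.157), by library 6.16, 2.10 and 6.24 against 1.36, 1.36 and 1.63 (two-sided exact permutation p = 0.1, the smallest possible, n = 3 per group). These fragments enter the authors' total for scaling and so lower every FPKM of the library. With scaling to the fragments of the listed genes, 51.9% of calls were raised in place of 40.6%, so the excess of lowered genes is consistent with this scaling. What the fragments are was not analysed here, and a real change in RNA content with NaB stays open.

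NaB replicate 2 stood apart from replicates 1 and 3. Its log2 difference from their mean correlated with gene GC content (Pearson r = 0.632 across genes, which are not independent replicates), and removing the GC trend lowered the SD of its differences from them, relative to that between replicates 1 and 3, from 1.89 to 1.22 times, so GC content may account for most but not all of the gap. The test of its label fixed beforehand decided nothing on its own: in 58.3% of the 5204 genes called without it, it lay nearer to the other NaB libraries than to GLT (80.1% after removal of the GC trend). A GLT library under its label is argued against by the slope across genes, after removal of the GC trend, of its difference from GLT on that of replicates 1 and 3, at least 0.604 where no GLT library exceeded 0.00938, and an exchange by the GLT libraries, whose largest SD from each other was 0.145, below the smallest SD of 0.302 between a GLT library and NaB replicate 1 or 3. A difference in the cells or in library preparation stays open.

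More genes held at least 10 fragments with NaB, 16583 on average against 15946. After thinning to 1 depth the difference was still 575 genes, beyond the SDs of 105 and 54.0, which argues against depth. Background from genomic DNA would have needed 542 olfactory receptor fragments per library by the ratio of fragments gained to lost, and the highest NaB library held 327, which argues against it. NaB itself may account for the rise, as a hypothesis found and tested on the same data.

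With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Every split but the real one mixes GLT and NaB libraries in both of its groups. A NaB difference then enters the spread within the groups, which leaves few calls by construction. The counts of called genes in other splits therefore do not show what chance alone gives. The real split gave 3147 called genes and the highest other 1, in 1 of 10 splits as many; the same numbers of splits held for at least 2-fold genes (104 against 1). Other splits have no direction, so their larger direction was set against the raised (1278 against 1) and the lowered genes (1869 against 1), again with 1 of 10 splits as many. For the gene lists, 4 of the 10 splits, the real one included, gave as many as the real 5, and the highest other gave 7. The number of lists past camera with the preset correlation was thus no higher in the real split than in the highest other. A part of a NaB difference can stay in the mixed splits, so these numbers of lists decide nothing about NaB.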

How the results depend on the processing

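Alternatives with GC correction or scaling to the listed genes were chosen after seeing the data. No gene called under the authors' scaling was called with the opposite sign in any of 21 settings, and 70 of 130 named genes past the threshold stayed past it in every setting that tested them. Called genes ranged from 1333 to 5204 with 1 library left out, raised from 650 to 1873, lowered from 683 to 3331, at least 2-fold from 104 to 120 and lists from 3 to 6; the low ends of the first 3 came without GLT replicate 3, and their high ends and the low end for lists without NaB replicate 2. The GC correction called 5110 genes, 2525 raised, kept 97.9% of the calls and passed 3 lists. With the replicate block as well it called 4605, of which 2295 raised. The block alone called 2537 genes and kept 76.2% of calls. Same-numbered libraries of the 2 groups deviated together by correlations of only 0.05, 0.02 and 0.02. These were still above those of every other pair across the groups, at -0.027 to 0.007. Correlations this small do not show a pairing by number and cannot exclude one for a part of the genes. The genes changed by NaB at least 2-fold were 254 and 278 with pseudocounts of 0.1 and 0.01, 225 as TPM, 290 with limma-voom and 37 with a mean FPKM of at least 5, where 687 were raised. Without a filter 1070 were lowered. Lists past the threshold were 0 with an estimated correlation and 9 with fry, which does not compare a list with other genes. Fry was run only under the authors' scaling, where the median log2 fold change of all tested genes was -0.04, so its downward results may hold a part of that shift. The cause was not tested, except that leaving out libraries reduces the samples and that a smaller pseudocount enlarges folds of low genes by construction. Fewer samples do not account for the rise to 5204 calls without NaB replicate 2. TFEB rested on 89 to 136 fragments per library, a counting error of 8.57% to 10.6%. Its log2 fold change ran from -0.32 to -0.13 over 20 settings and passed in none, and whether depth is the reason was not tested.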

Other observations

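The gene families in this part were chosen after their values were seen, from a scan of 134 groups of at least 10 tested protein-coding genes that share the letters of their symbol; 4 passed. Of the 36 tested genes of the PSMA, PSMB, PSMC and PSMD families, which encode proteasome subunits except for the assembly chaperones PSMD5, PSMD9 and PSMD10, 29 fell, 0 rose and 7 did not pass, a pool that was not itself tested as a list (median log2 fold change -0.46; 28 fell and 0 rose under median-ratio, TPM and quantile scaling). PSMB fell in 9 of 10 (camera adjusted p = 0.000246) and PSMD in 11 of 14 (7.76e-05), both with an adjusted p = 0.737 with an estimated correlation. Unadjusted for the 134 groups, camera with an estimated correlation gave p = 0.115 for PSMB and 0.00648 for PSMD. PSMB2, a subunit of the catalytic core, fell from 82.9 ± 1.92 to 45.6 ± 1.27 FPKM (SD, n = 3 per group), PSMB7 from 183 ± 1.40 to 116 ± 7.16 and the ATPase gene PSMC6 from 15.6 ± 0.159 to 9.72 ± 0.884. POMP, a proteasome assembly factor, fell from 90.9 ± 7.32 to 63.2 ± 5.74. Of the immunoproteasome subunits, PSMB10 fell from 7.09 ± 0.143 to 3.34 ± 0.590 and PSMB8 from 28.6 ± 1.16 to 22.2 ± 1.31, while PSMB9 stood at 14.8 ± 0.877 and 15.9 ± 1.35 and did not pass.

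Of 16 tested collagen genes, 11 rose, 1 fell (COL8A1) and 4 did not pass (median 0.37, the same counts under median-ratio, TPM and quantile scaling). The group by symbol, which also holds COL4A3BP, a lipid transfer gene that is no collagen, passed at a camera adjusted p = 7.76e-05. With an estimated correlation the adjusted p was 0.737 (unadjusted camera p = 0.109). COL7A1 rose from 28.1 ± 1.41 to 42.9 ± 5.15 FPKM and COL4A1 from 61.2 ± 0.996 to 78.8 ± 2.97. Genes of the large mitochondrial ribosomal subunit (MRPL) had 16 of 49 lower and 0 higher (median -0.18, camera adjusted p = 0.00156). With an estimated correlation their adjusted p was 0.737 (unadjusted camera p = 0.0457). In this family 1 was higher under median-ratio scaling, 2 under TPM and 3 under quantile normalization. MRPL9 fell from 20.9 ± 2.23 to 13.3 ± 0.509 FPKM.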
